A study of Homo sapiens with 9 samples.

How the data were processed

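The deposited table gives raw counts per gene row, 1 column for each of the 9 libraries, made by the authors before deposition from single 50 bp reads of TruSeq stranded mRNA libraries. The authors' notes name FastQC, TopHat2 2.0.12, Bowtie2 2.2.3, SAMtools 0.1.19, Cufflinks 2.2.1, HTSeq 0.6.1 and the build hg19. The strand setting used in counting, the annotation and any filter are not given in the sources used here. All 9 columns were used.

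Counts were analysed with edgeR 4.0.16 in R 4.3.3. Rows were kept by filterByExpr on the 3 groups (minimum count 10, minimum total 15), scaled by TMM, and tested with the robust quasi-likelihood F-test in 1 fit of all libraries by group. A row was called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of F. CPM are shown as mean and SD. Chance would give 184 rows at an unadjusted p under 0.05. The test, the named rows rule, the 38 gene lists and the first set of alternatives were chosen before the data were examined.

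Lists with at least 5 tested rows were tested with camera of limma 3.58.1 (preset correlation 0.01) on log2 CPM with a prior count of 2, with Benjamini-Hochberg over the lists of a comparison. Beside it stand camera with an estimated correlation, fry, and the count of members adjusted over the list alone.

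Named rows were, for each vesicle comparison, up to 7 highest and 7 lowest log2 fold changes among called rows with a mean of at least 2 CPM and groups that do not overlap, and 6 of each for the direct contrast, plus called members of up to 8 lists. Pseudogene-like and unnamed loci were passed over. The same kind of rule for the fit with the replicate block, with the same sign in all 3 same-numbered pairs in place of groups that do not overlap, was added after the data were seen.

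Rows were matched by name to GENCODE 29 on GRCh38 for their strand, overlaps and distances in nt from the 3′ end of the opposite gene. The deposited rows were counted on hg19, so no coordinates are given.

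Whether replicate numbers pair the samples was checked by correlating residuals from group means between groups. All same-numbered correlations were above the threshold of 0.1 (0.115 to 0.677), so a replicate block was fitted beside each comparison. Replicate 3 correlated with replicate 3 at 0.450 to 0.677. In replicates 1 and 2, the same number gave 0.115 to 0.328 and replicate 1 with replicate 2 of another group gave 0.133 to 0.350, so there the pairing is no closer than between numbers. The chi-square per degree of freedom of replicates 1 and 2 was 1.51 in controls and 2.41 in E. coli libraries, and within-group pairs with replicate 3 had 6.41 to 12.4. V. cholerae replicates 1 and 2 had 1.08 over their rows, close to sampling noise. They were kept as 2 libraries, and summed in an alternative.

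A self-test simulated 200 changed rows among the 3679 in the V. cholerae comparison. By group only, edgeR recovered 2 of 67 rows at 1.5-fold, 17 of 67 at 2-fold and 54 of 66 at 4-fold, with 1 false call. With the block it recovered 14 of 67, 41 of 67 and 61 of 66, with 3 false calls. The overlap of the vesicle comparisons was set against 50 simulated data sets with no effect.

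Alternatives were RLE factors, library size alone, no filter, a filter of CPM at least 5 in at least 3 libraries, a fit without the robust option, only the 2 groups compared, a log2 size of at least 1, limma voom, DESeq2 1.42.0, the replicate block and leaving out each library. Added after the data were seen were replicates 1 and 2 alone, V. cholerae replicates 1 and 2 summed, leaving out each library with the block kept (for called rows and for rows called in both comparisons), list membership by opposite gene, and the medians of all lists when each library was left out. Also added then were the 1744 rows with a coding gene opposite, without and with the trend over distance from the 3′ end removed. That trend was a lowess of span 0.3 per library. Floors of 3 counts and the 95% interval of the olfactory receptor ratio (Poisson) cover counting error only. The 95% intervals of distances and lengths come from 2000 bootstrap draws over rows, and that of the share of calls with the same sign is exact binomial over rows.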

Results

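HCT8 cells, an established human line from an ileocecal colorectal adenocarcinoma, were incubated for 5 h with membrane vesicles of Vibrio cholerae C6706, with membrane vesicles of Escherichia coli MC1061, or as a control. Membrane vesicles are small particles shed from the bacterial surface. The sample labels call the control untreated, and the protocol gives it as 20 mM Tris-HCl. Polyadenylated RNA was sequenced from 3 libraries per group, and the deposited table gives whole-number counts for 26008 gene rows. Total counts ran from 363557 in control replicate 1 to 733412 in V. cholerae replicate 3, and the other 7 libraries held 374515 to 477888. On the scale of the CPM given here (counts scaled by edgeR to the library total times its TMM factor, over the rows tested), 3 counts are worth 3.88 to 9.07 CPM, so rows near that level rest on few counts. A total of 15633 rows had at least 1 count, and the 3679 rows tested held 94.4% of all counts. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

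The counts lay mostly in rows that overlap another gene on the opposite strand. Of the 24769 rows matched to a gene of the GENCODE 29 annotation, 32.4% have exons that overlap exons on the other strand, and these rows held 85.9% of the matched counts. Among the 200 rows with the most counts, 184 were matched and 173 of those had such an overlap. Genes that every cell uses had few counts: GAPDH 33 to 63 per library, ACTB 21 to 34 and EEF1A1 14 to 37. The KRT18 row held 56 to 96 counts per library and the KRT8 row, whose exons lie opposite KRT18, held 7550 to 11346. The PPIB row held 1 to 8 counts and the SNX22 row opposite it 7680 to 15498, and the PCNA row held 0 to 7 counts and the PCNA-AS1 row opposite it 1158 to 2741. In 144 of 227 pairs of a coding and a non-coding row that overlap on opposite strands (63.4%), the non-coding row held more counts, with a median ratio of 3.58. Changed rows below are therefore named with the coding gene on their opposite strand where there is one, and which of these transcripts gave the reads is not settled by the table alone. The counts look like reads on the strand opposite each named gene, and the strand setting of the counting is not given in the sources used here. Values of rows and lists read by name, such as DNMT1, SOCS2 and the ribosomal proteins, are therefore not established as levels of those genes' own transcripts. Among genes with too few counts for a test, CXCL8 had 2 counts over the 9 libraries, CCL20 had 1, TNFAIP3 had 1, NFKBIA had 15, TET2 had 55, TLR5 had 1 and TLR4 had 0.

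**Figure D1:**
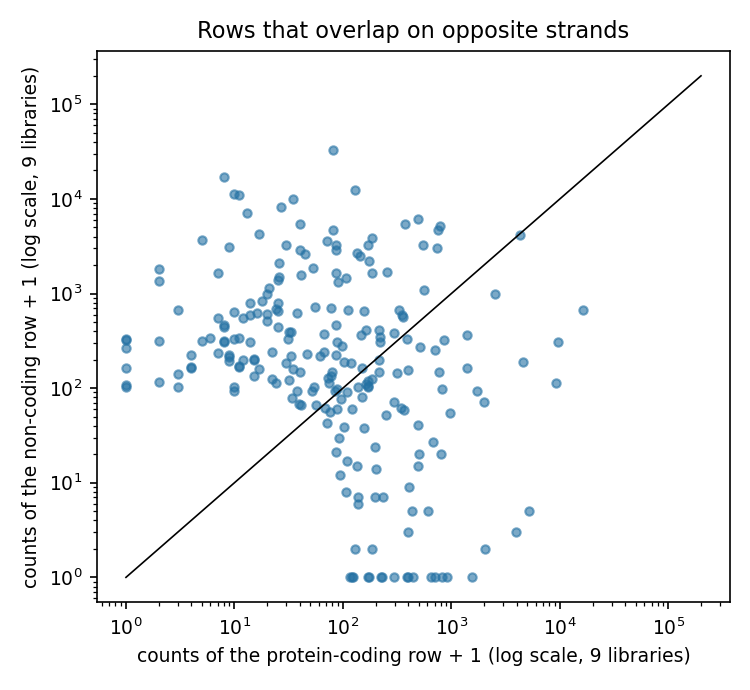
Total counts over the 9 libraries of 227 pairs of a protein-coding row (horizontal axis, log scale, plus 1) and a non-coding row (vertical axis, log scale, plus 1) that overlap on opposite strands, 1 point per pair. Points above the diagonal, 144 of the 227, are pairs whose non-coding row holds more counts.

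Replicate 3 of all groups stood apart from replicates 1 and 2. The first principal component of log2 CPM carried 35.2% of the variance and the second 28.7%. The 3 libraries of replicate 3 lay together, and E. coli replicates 1 and 2 lay away from the other 4 libraries of replicates 1 and 2. Rows without an opposite-strand exon held 15.9% to 16.1% of counts in replicate 3 and 12.1% to 13.3% in replicates 1 and 2. E. coli replicates 1 and 2 also differed in where along transcripts the counts lay. Counts in rows whose overlap lay at least 3000 nt from the 3′ end of the opposite coding gene came to 37.4% and 32.5% of the counts in rows under 500 nt from it, against 55.6% to 59.9% in the other 7 libraries. Rows of mitochondrial pseudogene sequence (MIR6723 and MIR4461) took 4.33%, 4.97% and 4.13% of counts in E. coli replicates 1, 2 and 3, 1.79%, 1.99% and 3.54% in the controls and 2.41%, 2.19% and 5.02% in the V. cholerae libraries. Same-numbered samples deviated from their group means together (correlations 0.115 to 0.677). Among replicates 1 and 2 the same number gave 0.115 to 0.328, and replicate 1 with replicate 2 of another group gave 0.133 to 0.350. A replicate block thus mainly sets replicate 3 apart, and a pairing of numbers 1 and 2 is not shown. Values from a fit with the replicate number as a block are given beside each result it changes, as are values from replicates 1 and 2 alone.

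**Figure D2:**
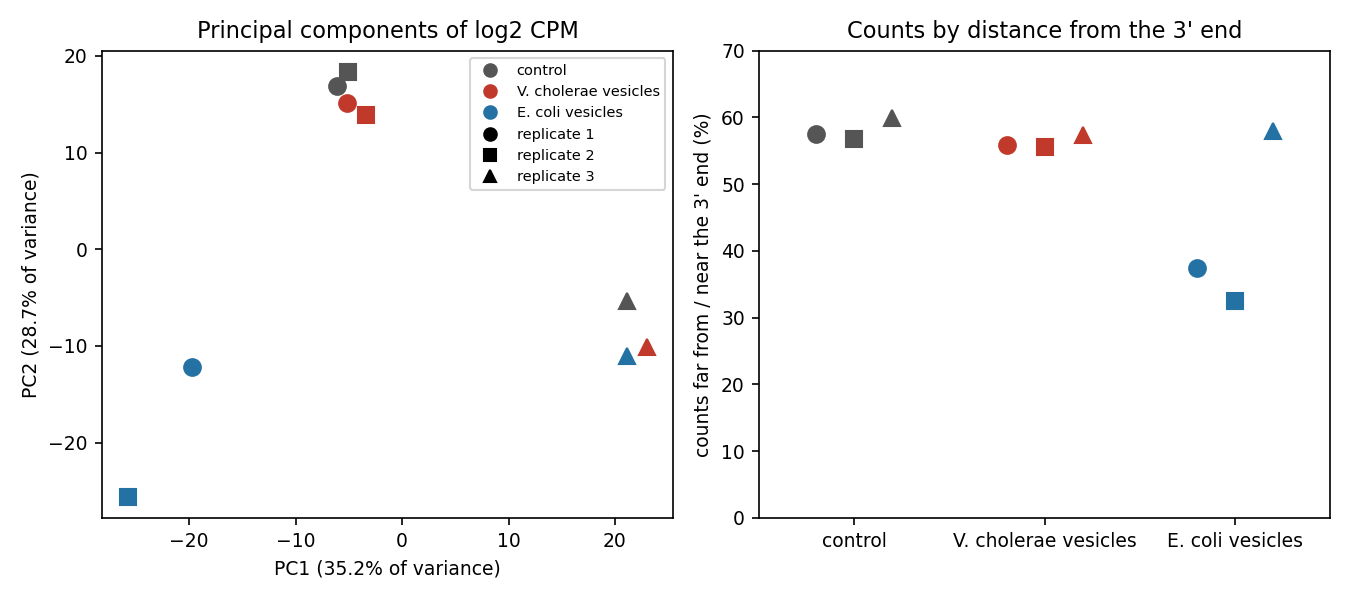
Left, the first and second principal components of log2 CPM of the tested rows, 1 point per library, with colour for the group and shape for the replicate. Right, counts in rows at least 3000 nt from the 3′ end of the opposite coding gene as a percent of counts in rows under 500 nt from it, where E. coli replicates 1 and 2 sit at 37.4% and 32.5% and the other 7 libraries at 55.6% to 59.9%.

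The series title names gene transcription and epigenetics under bacterial vesicles as its subject, and the first comparison asks which rows changed with V. cholerae vesicles against control. The planned fit, without the block, called 2 rows, given below. With the replicate block, 13 rows changed, 10 higher and 3 lower. The block takes out the offset of replicate 3, and edgeR's common dispersion was 0.0243 with it against 0.0690 without it. Part of the spread left is that between replicates 1 and 2, which may be technical. Summing V. cholerae replicates 1 and 2 was not repeated with the block. The blocked p-values of these 13 rows, and those below, may thus rest on too narrow a spread. The C5orf45 row (XLOC_019302) lies opposite SQSTM1, the autophagy receptor p62, and rose from 1540.3 ± 108 to 3946 ± 888 CPM (SD, n = 3), a log2 fold change of 1.32 ± 0.14 (SE). The NME7 row, opposite ATP1B1 of the sodium pump, rose from 1512 ± 331 to 3199.6 ± 139 CPM (SD, n = 3). The MYBBP1A row, opposite the sphingosine-1-phosphate transporter SPNS2, rose from 109 ± 11.2 to 247 ± 65.2 CPM (SD, n = 3), and the CBR3-AS1 row, opposite the carbonyl reductase CBR3, had a log2 fold change of 1.14 ± 0.19. The KRT8 row, opposite the epithelial keratin KRT18, fell from 27982 ± 5362 to 19946 ± 5064 CPM (SD, n = 3), a log2 fold change of -0.50 ± 0.08.

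The PP7080 and SLC9A3 rows, both opposite the exocyst subunit EXOC3, rose by log2 1.32 ± 0.18 and 0.80 ± 0.11, and the TAPSAR1 row, opposite the antigen-processing genes TAP1 and PSMB8, rose by 0.70 ± 0.13. The PCSK7 row, opposite the actin-binding protein gene TAGLN, fell from 102.2 ± 42.0 to 33.1 ± 10.9 CPM (SD, n = 3). The IFNLR1 row, named for a subunit of the interferon lambda receptor and without an opposite-strand exon, fell from 158 ± 27.1 to 38.4 ± 16.3 CPM (SD, n = 3), a log2 fold change of -1.93 ± 0.29 with the block and -1.95 ± 0.34 without it. The B3GALT6 row, named for a glycosaminoglycan galactosyltransferase, rose from 8.26 ± 4.90 to 74.2 ± 21.7 CPM (SD, n = 3), a log2 fold change of 3.06 ± 0.44 with the block and 3.09 ± 0.47 without it. The MCAT row rose by log2 2.27 ± 0.45 with the block, from 3, 2 and 5 counts in the controls, so its size rests on few counts. SLC9A3 and TAPSAR1 fell outside the rules for named rows and were chosen after their values were seen.

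Without the block, edgeR's quasi-likelihood test called 2 of the 3679 rows at a Benjamini-Hochberg adjusted p under 0.05, B3GALT6 (adjusted p = 0.0149) and IFNLR1 (adjusted p = 0.0392). DESeq2 called 4 and limma voom 0, and 100 rows had an unadjusted p under 0.05, where chance gives 184. Replicates 1 and 2 alone gave 70 rows, 43 higher and 27 lower, of which 61 (87.1%) had the same sign in replicate 3, against 57.5% of all rows tested. Their chi-square per degree of freedom within groups was 1.08 for V. cholerae, 1.51 for control and 2.41 for E. coli libraries, against 6.41 to 12.4 with replicate 3. The p-values of that fit thus measure a narrow spread that may be technical. The count without the block was 0 when control replicate 1, control replicate 2 or V. cholerae replicate 2 was left out, 1 without V. cholerae replicate 1, 5 without V. cholerae replicate 3 and 4 without E. coli replicate 3. With the block it was 4 or 5 without control replicate 1 or 2 or V. cholerae replicate 1 or 2, 26 without E. coli replicate 2 and 77 without E. coli replicate 3. The DNMT1 row, of the maintenance DNA methyltransferase, stood at 58.5 ± 6.06 CPM in controls and 53.1 ± 9.45 CPM with V. cholerae vesicles (SD, n = 3), and its log2 fold change of -0.16 ± 0.36 did not pass the test.

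**Figure D3:**
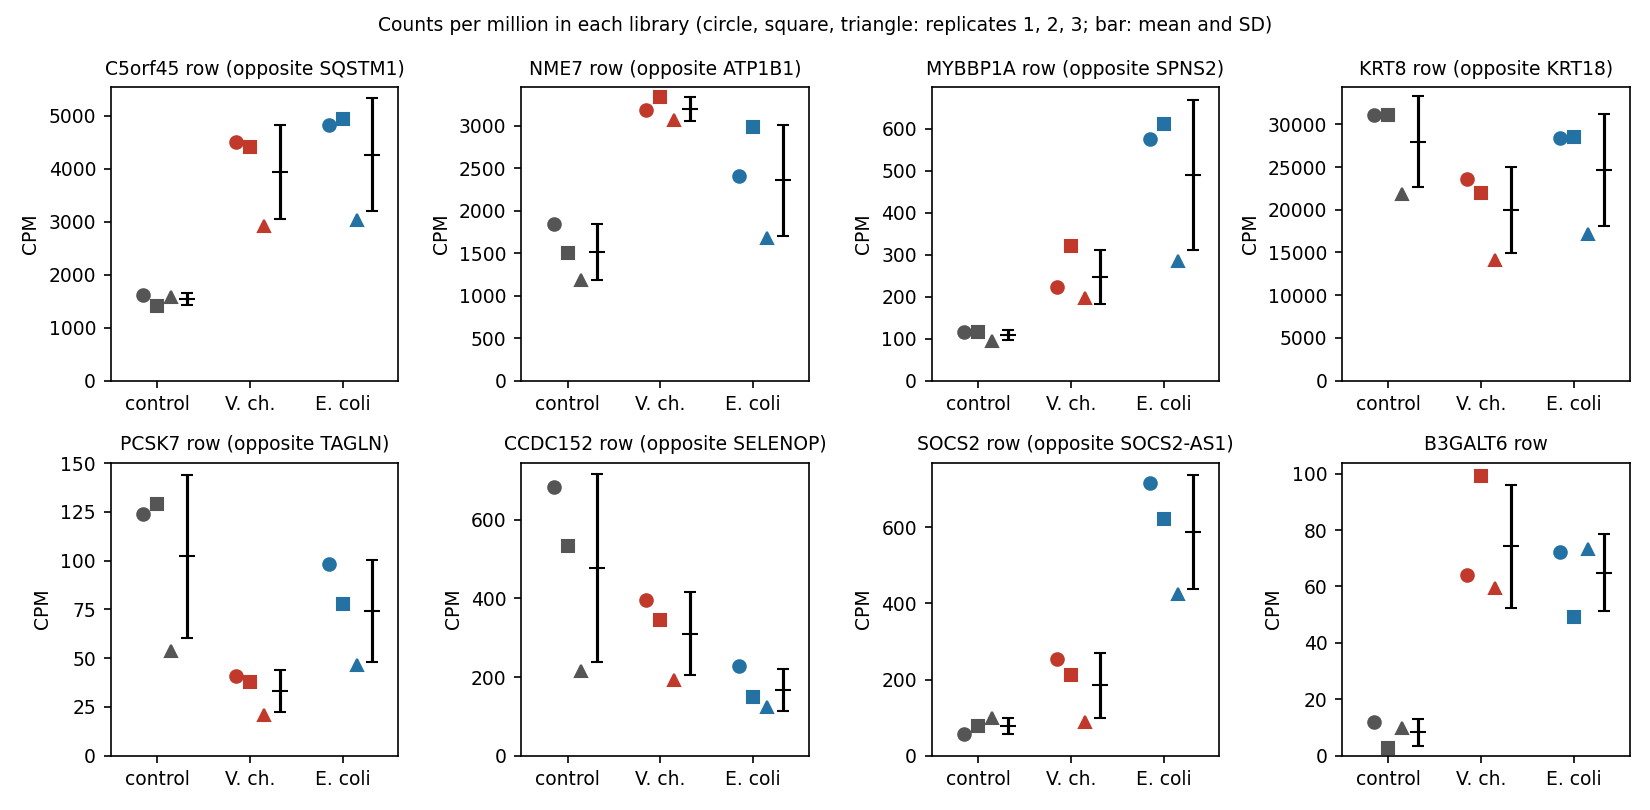
CPM (vertical axes, from 0) of 8 named rows in each of the 9 libraries by group, with circles, squares and triangles for replicates 1, 2 and 3 and bars for the group mean and SD (n = 3). The C5orf45 row opposite SQSTM1 stands at 1540.3 ± 108 CPM in controls, 3946 ± 888 CPM with V. cholerae vesicles and 4268 ± 1069 CPM with E. coli vesicles.

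With E. coli vesicles against control, 7 rows changed without the block, all higher. The SOCS2 row (XLOC_005303), named for a suppressor of cytokine signalling and opposite SOCS2-AS1, rose from 77.9 ± 21.1 to 587 ± 149 CPM (SD, n = 3), a log2 fold change of 2.89 ± 0.37 (edgeR adjusted p = 9.9e-04). The MYBBP1A row opposite SPNS2 rose to 490.2 ± 179.5 CPM (SD, n = 3), log2 2.17 ± 0.32, and the C5orf45 row opposite SQSTM1 to 4268 ± 1069 CPM (SD, n = 3), log2 1.47 ± 0.26. The C11orf68 row rose from 84.0 ± 46.3 to 475 ± 33.0 CPM (SD, n = 3), and the CCDC85B row rose from 111 ± 23.3 to 354 ± 116 CPM (SD, n = 3). The B3GALT6 row rose to 64.8 ± 13.7 CPM (SD, n = 3), and the seventh, LOC100130238, which the naming rule passes over, rose by log2 3.14 ± 0.57.

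With the replicate block 84 rows changed in the E. coli comparison, 54 higher and 30 lower, and 59 of them had a coding gene opposite. Among the rows higher were ATP2C2, of a secretory-pathway calcium pump and opposite ATP2C2-AS1 (log2 1.61 ± 0.27), CHMP2B, of membrane scission (1.76 ± 0.41), MCAT (2.03 ± 0.47) and P4HA2-AS1, opposite the collagen prolyl hydroxylase P4HA2 (0.72 ± 0.16). Rows lower included CCDC152, opposite the selenium transporter SELENOP, at 477 ± 239 CPM in controls and 167 ± 54.2 CPM with E. coli vesicles (SD, n = 3). They also included the row of the glucose transporter SLC2A1 opposite SLC2A1-AS1 (log2 -1.56 ± 0.32) and SMIM19 opposite the phosphate transporter SLC20A2 (-1.71 ± 0.41). FAM120A opposite FAM120AOS (-1.74 ± 0.40), TRIM44 (-1.49 ± 0.34) and LY6K opposite LNCOC1 (-1.47 ± 0.37) were lower too. Several of these rows rest on few counts. In the 3 controls MCAT held 3, 2 and 5 counts and CHMP2B 1, 10 and 10. In the 3 E. coli libraries SLC2A1 held 9, 6 and 26 counts, SMIM19 7, 3 and 12 and FAM120A 7, 2 and 5. TRIM44 held 7, 5 and 8 there and LY6K 6, 7 and 8. PCNA-AS1 opposite the replication clamp PCNA stood at -0.59 ± 0.12, ENOSF1 opposite thymidylate synthase TYMS at -0.43 ± 0.09 and HMMR-AS1 opposite the mitotic gene HMMR at -0.84 ± 0.16.

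Of these 84 rows, the 22 lower rows with a coding gene opposite lay a median of 3019 nt from its 3′ end and the 37 higher ones 437 nt. Replicates 1 and 2 alone, with the narrow spread given above, gave 804 rows, 363 higher and 441 lower. Of these, 531 (66.0%) had the same sign in replicate 3, against 56.4% of all rows tested. Across the 1744 rows with a coding gene opposite, the log2 fold change of replicates 1 and 2 had a Spearman correlation of -0.427 with the distance from the 3′ end, and the ratio of the replicate 3 libraries one of -0.110. In the V. cholerae comparison the values were -0.00960 in replicates 1 and 2 and -0.114 in replicate 3. These correlations are across rows, which are not independent replicates. Over those 1744 rows the block gave 42 rows, and 51 with the trend over this distance removed, 38 of which were among the 84. The direction of the calls depended on the method. DESeq2 called 35 rows, 13 higher and 22 lower, the fit with no filter 40, 10 higher and 30 lower, and limma voom 5. Of the 3679 rows, 414 had an unadjusted p under 0.05. The count of 7 became 4 without control replicate 1, 3 without control replicate 2, 10 without control replicate 3, 4 without E. coli replicate 1 or 2, 11 without V. cholerae replicate 3 and 236 without E. coli replicate 3. The blocked count became 5 and 3 without control replicates 1 and 2, 32 and 55 without V. cholerae replicates 1 and 2, 9 and 37 without E. coli replicates 1 and 2, and 817 without E. coli replicate 3. DNMT1 stood at 38.3 ± 19.2 CPM with E. coli vesicles (SD, n = 3), a log2 fold change of -0.57 ± 0.38 that did not pass the test. For DNMT1 it was -1.16 in replicates 1 and 2 only (edgeR adjusted p = 0.0270, where the alternatives ran to 0.993), -1.08 without E. coli replicate 3 and -0.33 without E. coli replicate 2, and the log2 ratio of the replicate 3 libraries was 0.19.

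**Figure D4:**
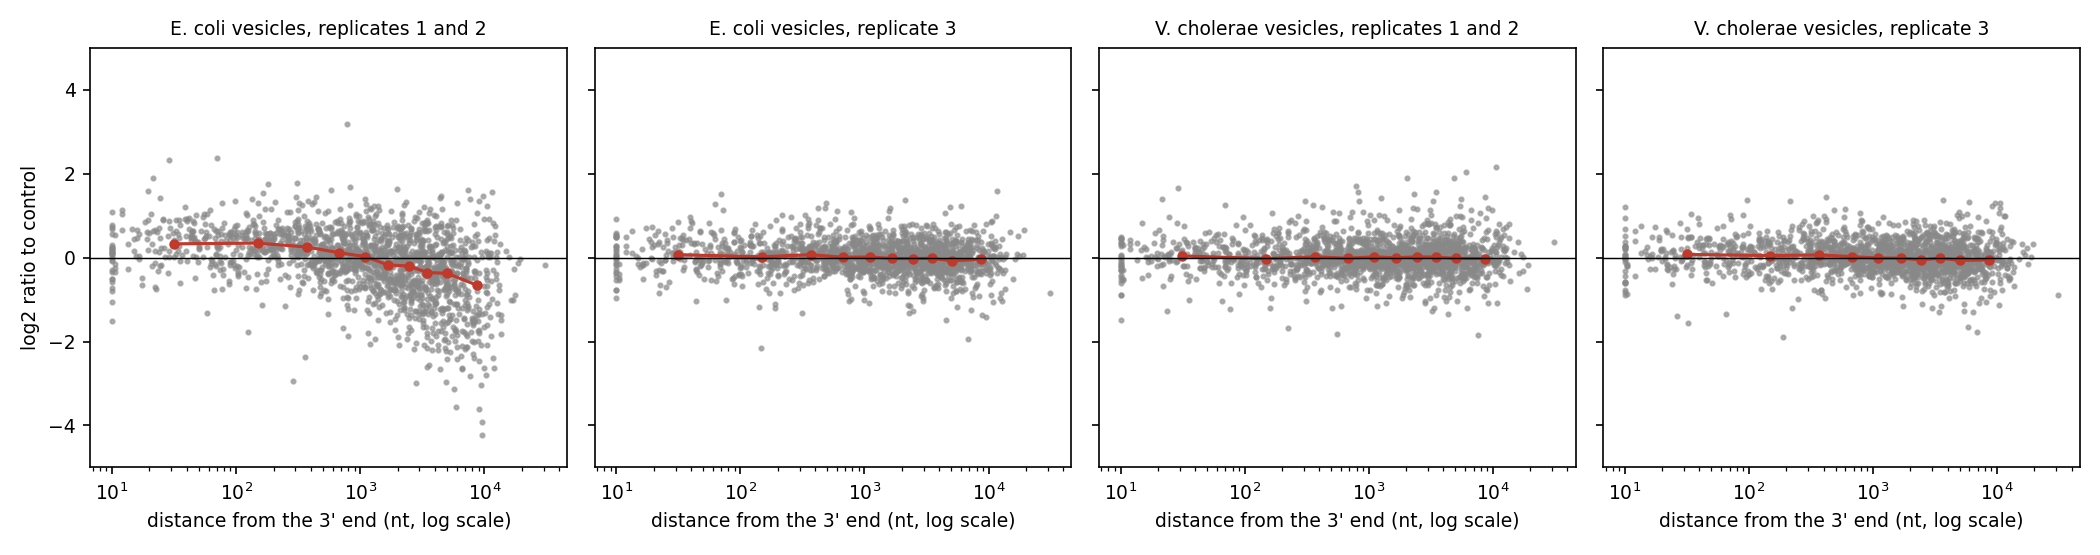
Log2 ratio to control (vertical axis) of the 1744 rows with a coding gene opposite against the distance from the 3′ end of that gene (horizontal axis, nt, log scale, with distances under 10 nt drawn at 10), 1 grey point per row and a red line through the medians of 10 equal bins of rows. The Spearman correlation is -0.427 in E. coli replicates 1 and 2, -0.110 in E. coli replicate 3, -0.00960 in V. cholerae replicates 1 and 2 and -0.114 in V. cholerae replicate 3.

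The direct contrast of V. cholerae with E. coli vesicles asks whether the responses to the vesicles differed. Without the block edgeR called 0 rows, with 333 at an unadjusted p under 0.05, DESeq2 5 and limma voom 0. With the block the C11orf68 row, at 160 ± 17.2 CPM with V. cholerae and 475 ± 33.0 CPM with E. coli vesicles (SD, n = 3), and the BAZ2A row opposite the RNA-binding protein gene RBMS2, at 82.2 ± 15.04 and 229 ± 86.4 CPM (SD, n = 3), were lower with V. cholerae vesicles. Their log2 differences were -1.58 ± 0.24 (edgeR adjusted p = 0.0212) and -1.41 ± 0.24 (adjusted p = 0.0449). Replicates 1 and 2 alone, with the same narrow spread, gave 766 rows. Of these, 438 (57.2%) had the same sign in replicate 3, against 53.1% of all rows tested, and 54% of the 50 rows with the smallest p did. Among those with a coding gene opposite, the 240 lower rows lay a median of 380 nt from its 3′ end and the 286 higher ones 3468 nt. The Spearman correlation of the log2 difference with that distance, over 1744 rows, was 0.444 in replicates 1 and 2 and 0.00871 in replicate 3. The BAZ2A row lies 301 nt from the 3′ end. Over the rows with a coding gene opposite alone, the block called 0 rows with or without the position correction, so the BAZ2A call ended there. Leaving out E. coli replicate 3 raised the count to 204 without the block and 747 with it, leaving out control replicate 3 raised that without the block to 1, leaving out V. cholerae replicate 3 raised the blocked count to 39 and leaving out control replicate 3 raised it to 5. The blocked count was 1 without control replicate 2 and 0 without V. cholerae replicate 1 or 2 or E. coli replicate 1. For SOCS2, called in the E. coli comparison only, the difference between the vesicle groups was not called. DNMT1 differed by log2 0.41 ± 0.38, which did not pass the test. For DNMT1 this was 1.08 in replicates 1 and 2 only (edgeR adjusted p = 0.0464, where the alternatives ran to 0.999), 0.92 without E. coli replicate 3 and 0.17 without E. coli replicate 2.

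Of 38 gene lists chosen before the data were examined, 19 had at least 5 tested rows by name, and 3 changed with V. cholerae vesicles by limma's camera test, all lower. Lists by name hold rows whose reads may come from the opposite strand. Rows named for genes of G1/S and DNA replication had a median log2 fold change of -0.33, with 11 of 12 rows lower (adjusted p = 0.00213, and adjusted p = 0.153 with an estimated correlation). Among them were the rows of CHAF1A, a chromatin assembly factor gene opposite UBXN6, at -1.24 ± 0.48, of cyclin D1 gene CCND1, opposite LTO1, at -0.64 ± 0.32 and of the helicase subunit MCM3 at -0.47 ± 0.42. Rows named for SRF and actin cytoskeleton genes had a median of -0.28, with 9 of 10 rows lower (adjusted p = 0.00354, and adjusted p = 0.593 with an estimated correlation), among them the ACTG1 row at -1.25 ± 0.41 and the FLNA row at -1.08 ± 0.41. Rows named for ribosomal protein genes had a median of -0.30, with 28 of 32 rows lower (adjusted p = 0.00213, and adjusted p = 0.709 with an estimated correlation). These 32 rows are part of a list that held 0.223% of all counts. These examples were chosen after their values were seen. In these 3 lists 0 rows were called over all rows tested and 0 adjusted over the list alone without the block. With the block 0 rows were called over all rows tested, and 2 SRF and actin rows were lower adjusted over the list alone. Without V. cholerae replicate 3 camera called 0 lists, and the SRF and actin median was -0.03 and the ribosomal protein median -0.08.

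With E. coli vesicles camera called 0 of the 19 lists by name, with adjusted p from 0.610 to 0.891, while limma's fry test called 0 and camera without E. coli replicate 3 called 1. In the direct contrast the rows named for ribosomal protein genes were lower with V. cholerae than with E. coli vesicles, with 28 of 32 rows lower and a median of -0.34 (adjusted p = 0.00113, and adjusted p = 0.748 with an estimated correlation). That call ended without V. cholerae replicate 3, E. coli replicate 1 or E. coli replicate 2, and the summed CPM of ribosomal protein rows was 2705, 2890.2 and 1846 in E. coli replicates 1, 2 and 3.

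The other 16 lists tested by name did not pass in any comparison by camera or fry, and their medians are given as values for V. cholerae and for E. coli vesicles against control. Inflammatory and innate immune lists stood at 0.19 and 0.16 for NF-kB pathway genes, 0.34 and -0.15 for interferon-stimulated genes and 0.32 and 0.28 for pattern recognition receptors. Stress lists stood at 0.03 and 0.32 for endoplasmic reticulum chaperones, -0.19 and -0.06 for heat shock genes, 0.14 and -0.14 for NRF2 targets, 0.19 and 0.21 for p53 targets, -0.03 and 0.16 for apoptosis regulators and -0.14 and -0.20 for autophagy and lysosome genes. Metabolic lists stood at -0.10 and 0.11 for hypoxia and glycolysis genes and 0.44 and 0.29 for cholesterol synthesis genes. Chromatin lists stood at 0.08 and 0.05 for histone modifying enzymes and -0.22 and -0.14 for chromatin remodelling complexes. Junction genes stood at 0.17 and -0.41, splicing and export factors at -0.08 and -0.11 and proteasome subunits at 0.14 and -0.13. Their adjusted p ran from 0.317 to 0.965 for V. cholerae vesicles, and medians and tests differed in sign for p53 targets, apoptosis regulators and histone modifying enzymes there and for NRF2 targets and splicing factors with E. coli vesicles. With 1 library left out, the sign of the median changed at least once in 9 of these 16 lists for V. cholerae vesicles and in 8 for E. coli vesicles.

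The 19 lists with fewer than 5 tested rows by name were not tested by name. Tested rows numbered 4 for each of fatty acid synthesis, G2/M and mitosis, mucins and antimicrobial genes, intestinal differentiation, Wnt targets and oxidative phosphorylation, and 3 for each of cytokines and chemokines, metallothioneins and YAP and TAZ targets. They numbered 2 for each of ATF4 and CHOP targets, DNA methylation enzymes and endothelial markers, and 1 for each of immediate early genes, TGF-beta and mesenchymal genes and leukocyte markers. They numbered 0 for mitochondrially encoded genes, replication-dependent histones, short-lived mRNAs and fibroblast markers. All the counts of leukocyte, fibroblast and endothelial marker rows together with the rest of their lists came to 405, 72 and 548.

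With list membership taken from the coding gene opposite each row, an alternative chosen after the data were seen, 11 lists could be tested. Rows opposite G1/S and DNA replication genes were lower in both vesicle groups. With V. cholerae vesicles 7 of 7 rows were lower, with a median of -0.68 (adjusted p = 5.0e-04, and adjusted p = 0.0625 with an estimated correlation), and with E. coli vesicles 6 of 7, with a median of -0.50 (adjusted p = 0.01003, and adjusted p = 0.156 with an estimated correlation). Among them are the rows opposite E2F2, GINS2, TYMS, CHAF1A, PCNA and CCNE2. With the block, 5 rows passed adjusted over the list alone in each comparison, and over all rows tested 0 did with V. cholerae vesicles and 3 did with E. coli vesicles, among them those opposite TYMS and PCNA. In replicates 1 and 2 alone the medians were -0.52 and -0.59. With the block the V. cholerae median of -0.68 was -0.36 without control replicate 2, with 6 of 7 rows lower. The direct contrast gave a median of 0.06 (limma camera adjusted p = 0.667).

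Rows opposite intestinal differentiation genes, among them KRT8, KRT18, VIL1 and EZR, were all lower with V. cholerae vesicles, with a median of -0.36 (limma camera adjusted p = 0.0714). They passed with the block at a median of -0.35 (adjusted p = 0.0169, and adjusted p = 0.215 with an estimated correlation). The KRT8 and KRT18 rows lie opposite each other, so they are not independent members, and the KRT18 row held 56 to 96 counts per library. The median without the block was -0.19 without V. cholerae replicate 3 and -0.59 without control replicate 3, with 4 of 5 rows lower in the latter. With the block 2 rows passed adjusted over the list alone and 1 over all rows tested. For E. coli vesicles their median was -0.18 (limma camera adjusted p = 0.962), and it ran from -0.33 without control replicate 3 to 0.04 without E. coli replicate 3, and was 0.03 with the position correction. By camera the remaining 9 lists by opposite gene did not pass with or without the block, and by limma's fry test hypoxia and glycolysis genes passed with V. cholerae vesicles and the block (adjusted p = 0.0363). Their medians without the block, for V. cholerae and then E. coli vesicles, with the range when 1 library was left out in brackets, were 0.11 (0.02 to 0.71) and 0.22 (-0.01 to 0.86) for endoplasmic reticulum chaperones, 0.17 (-0.06 to 0.28) and -0.01 (-0.08 to 0.31) for hypoxia and glycolysis and -0.02 (-0.34 to 0.08) and -0.77 (-0.91 to -0.68) for fatty acid synthesis. They were -0.11 (-0.30 to 0.04) and -0.40 (-0.56 to -0.24) for G2/M and mitosis, 0.23 (0.09 to 0.28) and 0.12 (-0.04 to 0.28) for p53 targets and 0.09 (0.02 to 0.14) and -0.01 (-0.36 to 0.15) for histone modifying enzymes. The last were -0.11 (-0.29 to 0.02) and -0.10 (-0.30 to 0.05) for splicing factors, -0.11 (-0.20 to 0.05) and 0.18 (0.08 to 0.28) for ribosomal proteins and 0.16 (0.07 to 0.23) and 0.18 (0.03 to 0.19) for oxidative phosphorylation. With 1 library left out, the sign of the median changed at least once in 5 of these 9 lists in each vesicle comparison.

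The vesicle comparisons share the 3 control libraries, so their calls overlap by chance more than independent lists would. Without the block 1 row, B3GALT6, was called in both, and with the block 9 rows were called in both, all higher. The blocked count was 1 without control replicate 1 or 2, 3 without V. cholerae replicate 1 or E. coli replicate 1, 4 without V. cholerae replicate 2 and 38 without E. coli replicate 3. Among the 9 were B3GALT6, MCAT and the rows opposite SQSTM1, SPNS2, ATP1B1, CBR3, EXOC3 (PP7080) and TAP1 with PSMB8 (TAPSAR1). Independent lists of the blocked sizes would share 0.147 higher and 0.0245 lower rows, and the highest of 50 simulated data sets with no effect shared 1. With no effect in either comparison few rows can be called at all. These data sets therefore cannot say how many rows the shared controls would bring together at the blocked sizes. The covariance of the fold changes was 0.0865 without the block, against a simulated mean of 0.0915 (SD 0.00358), a difference of -0.00504. With the block it was 0.0883 against 0.0564 (SD 0.00245), a difference of 0.0319. The correlations were 0.464 and 0.480, where the simulations gave 0.501 and 0.507, so by correlation there was no excess. The controls are too few to be split into groups of at least 2 libraries. Part of the shared calls and of the blocked difference in covariance may therefore come from the shared controls. Of the 9 shared rows, the direct contrast called 0 with the block, with adjusted p from 0.0683 for MYBBP1A to 0.854 for B3GALT6.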

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

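The tests of depth, genomic DNA, degradation in replicate 3, own-strand reads, exchanged labels, composition scaling and the left-out control library were chosen after the results were seen, as were the position correction and membership by opposite gene.

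A test of the difference between the vesicle groups drew attention to the C11orf68 row, with a log2 difference of -1.58155 between V. cholerae and E. coli vesicles with the replicate block, to the BAZ2A row opposite RBMS2, at -1.41308 and 301 nt from the 3′ end, and to the ribosomal protein list, with a median of -0.34082. Over the rows with a coding gene opposite alone, the BAZ2A call ended, with or without the position correction. The list's adjusted p was 0.748 by limma camera with an estimated correlation, and its call ended without V. cholerae replicate 3, E. coli replicate 1 or E. coli replicate 2.

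With 3 samples a group, the 10 splits of 6 libraries, or the 4 that part all same-numbered pairs, are too few for a share under 0.05. For V. cholerae vesicles 1 of 10 splits gave as many rows as the real one (real 2, highest other 0), 2 of 10 as many lists (real 3, highest other 3) and 1 of 4 as many with the block (real 13, highest other 0). For E. coli vesicles the splits were 1 of 10 for rows (real 7, highest other 0), 10 of 10 for lists (real 0, highest other 2) and 1 of 4 with the block (real 84, highest other 0). In the direct contrast they were 10 of 10 for rows (real 0, highest other 0), 7 of 10 for lists (real 1, highest other 4) and 1 of 4 with the block (real 2, highest other 0).

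Replicate 3 of all groups stood apart. Thinned to equal depth, its within-group pairs kept a median chi-square per degree of freedom of 7.524, where pairs of replicates 1 and 2 had at most 2.313, which argues against depth. Genomic DNA may account for rows of few counts, since olfactory receptor rows held 1.932 times the share in replicate 3 (95% interval 1.391 to 2.696, 90 against 66 counts in 420 rows), but not for rows of at least 100 counts, where the lowest value was 13.15 against at most 4.218. For degradation, the lowest correlation between groups of the replicate 3 differences was 0.4273 after the trend with position was removed and 0.3824 before. It cannot decide, since control and V. cholerae libraries had little trend to remove. Counts at least 3000 nt from the 3′ end were 59.9% and 57.4% of those under 500 nt in their replicate 3. In their replicates 1 and 2 they were 55.6% to 57.5%, so a loss by position in these groups was small. Other kinds of degradation were not tested. An earlier comparison of 18 higher and 2 lower rows gave an interval of -2937.68 to 1629.9 nt, too wide to decide. More own-strand reads would raise the 34 ribosomal protein rows without an opposite exon, whose highest ratio was 0.9261. All rows without an opposite-strand exon together went the other way, at 15.9% to 16.1% of counts in replicate 3 and 12.1% to 13.3% in replicates 1 and 2. More own-strand reads are thus not settled, and a difference in preparation stays open and untested.

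E. coli replicates 1 and 2 gave 804 calls, of which 66.0% had the same sign in replicate 3, against 56.4% of all rows. Among calls opposite coding genes, the 295 that fell lay a median 3037.51 nt farther from the 3′ end than the 262 that rose (95% interval 2699.24 to 3488.73), so degradation of RNA in these libraries may account for part of them. Of the 804 calls, 557 had a coding gene opposite. With the trend over this distance removed, replicates 1 and 2 still gave 492 calls over the 1744 such rows, 256 higher and 236 lower. Many calls thus remained without the trend, but how many of the 557 were among them was not counted. The share of the calls that the trend accounts for is therefore not settled. Both counts rest on the narrow spread of replicates 1 and 2. The opposite genes of rows that fell were also longer by a median of 1218 nt (95% interval 460.925 to 1745). Across the 1744 rows the log2 fold change had a Spearman correlation of -0.0879 with that length, against -0.427 with the distance. Loss of long transcripts stays open, but the changes followed length less closely than distance. An exchange of the replicate 3 vesicle labels would turn the signs of the direct contrast, and 57.1116% of 457 position-corrected calls kept theirs (95% interval 52.4% to 61.7%, over rows that are not independent; uncorrected, 57.2% of 766 calls and 53.1% of all rows did). A vesicle effect on RNA stability that replicate 3 lacks was not tested.

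Rows opposite G1/S and DNA replication genes were lower in both vesicle groups. With library size alone the higher of the medians was -0.527296, without 1 control library the highest was -0.493823 by group only and -0.361 with the block (V. cholerae vesicles without control replicate 2, 6 of 7 rows lower, from -0.679), and with the trend over position removed the higher was -0.611534. Scaling and a single control thus do not account for the whole of it, though control replicate 2 moved its size. With E. coli vesicles, loss by position does not either. There the log2 fold change of replicates 1 and 2 had a Spearman correlation of -0.427 with the distance. With V. cholerae vesicles it was -0.00960 in replicates 1 and 2 and -0.114 in replicate 3. With so little trend to remove, the test cannot decide for V. cholerae vesicles. Other kinds of degradation were not tested. The 7 rows lay a median 1094.5 nt from the 3′ end, against 1339.1 nt over all 1744 rows. A lower expression of replication genes in cells that met vesicles may be the reason, as a hypothesis found and tested on the same data, with adjusted p = 0.0625 and 0.156 by limma camera with an estimated correlation, and with the controls shared by both comparisons.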

How the results depend on the processing

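Replicates 1 and 2 alone, V. cholerae replicates 1 and 2 summed, leaving out libraries with the block kept, the rows with a coding gene opposite, the position correction and lists by opposite gene were chosen after the data were seen. The cause of the changes below was not tested. On the scale of the CPM given, 3 counts are worth 3.88 to 9.07 CPM, and the self-test recovered 17 of 67 changes of 2-fold by group only and 41 of 67 with the block.

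Called rows in the V. cholerae, E. coli and direct comparisons were 2, 7 and 0. They were 13, 84 and 2 with the replicate block, 5, 40 and 31 with no filter, 2, 7 and 3 with the stricter filter of CPM at least 5 in at least 3 libraries (strict in name alone, since it kept 8656 rows), 4, 35 and 5 by DESeq2, 0, 5 and 0 by limma voom, and 2, 7 and 1 with only the 2 groups compared. They were 3, 6 and 0 with library size alone, 2, 7 and 0 with RLE factors, without the robust option or at a log2 size of at least 1, 70, 804 and 766 in replicates 1 and 2 only, and 1, 7 and 0 with V. cholerae replicates 1 and 2 summed. DESeq2 called 13 higher and 22 lower rows for E. coli vesicles and the fit with no filter 10 higher and 30 lower, where the fit by group called 7 higher. Rows with a coding gene opposite gave 0, 2 and 0, with the block 9, 42 and 0, with the position correction 2, 2 and 0, with both 9, 51 and 0, and with the correction in replicates 1 and 2 only 44, 492 and 457. Leaving out 1 library gave 0 to 5, 3 to 236 and 0 to 204.

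With the block kept, the V. cholerae count of 13 was 5 without control replicate 1 or 2, 4 without V. cholerae replicate 1, 5 without V. cholerae replicate 2, 26 without E. coli replicate 2 and 77 without E. coli replicate 3. The E. coli count of 84 was 5 and 3 without control replicates 1 and 2, 32 and 55 without V. cholerae replicates 1 and 2, and 9, 37 and 817 without E. coli replicates 1, 2 and 3. The direct count of 2 was 1 and 5 without control replicates 2 and 3, 0, 0 and 39 without V. cholerae replicates 1, 2 and 3, and 0 and 747 without E. coli replicates 1 and 3.

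Lists called were 3, 0 and 1. They were 0, 0 and 0 with an estimated correlation, 1, 0 and 0 by fry, 2, 0 and 0 with the stricter filter, 1, 1 and 0 by opposite gene and 2, 1 and 0 by opposite gene with the block. Leaving out 1 library gave 0 to 3, 0 to 1 and 0 to 2, with 0 V. cholerae lists without V. cholerae replicate 3 and 1 E. coli list without E. coli replicate 3. In the direct contrast 2 were called without V. cholerae replicate 1 and 0 without V. cholerae replicate 3 or E. coli replicate 1 or 2. Without V. cholerae replicate 3 the SRF and actin median for V. cholerae vesicles was -0.03 (from -0.28) and the ribosomal protein median -0.08 (from -0.30). By opposite gene, the chaperone medians for V. cholerae and E. coli vesicles were 0.71 and 0.86 without control replicate 3 (from 0.11 and 0.22). Of the other medians by opposite gene, that of G2/M and mitosis ran from -0.30 without V. cholerae replicate 2 to 0.04 without V. cholerae replicate 3 for V. cholerae vesicles, and from -0.56 without control replicate 3 to -0.24 without E. coli replicate 3 for E. coli vesicles.

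Rows called in both comparisons were 1, and 9 with the block, 2 with library size alone, 37 in replicates 1 and 2 only and 0 to 4 with 1 library left out (0 without control replicate 1 or 2 or V. cholerae replicate 2, 4 without V. cholerae replicate 3, 3 without E. coli replicate 3). With the block the 9 rows called in both were 1 without control replicate 1 or 2, 3 without V. cholerae replicate 1, 4 without V. cholerae replicate 2, and 3 and 38 without E. coli replicates 1 and 3. The covariance of the vesicle fold changes, 0.0865, was 0.241 with the stricter filter, 0.1393 in replicates 1 and 2 only and 0.06549 to 0.256 with 1 library left out, the highest without control replicate 3.

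Of single rows, the DNMT1 difference with V. cholerae vesicles ran from -0.2896 to 0.005947 with 1 library left out, changing sign without V. cholerae replicate 3. The DNMT1 values ran over all alternatives from -1.162 to -0.3262 for E. coli vesicles and from 0.1692 to 1.077 in the direct contrast, each passing in 1 of 20, replicates 1 and 2 only. B3GALT6 with V. cholerae vesicles lost its call in 4 of 20 alternatives and IFNLR1 in 8 of 20, while SOCS2 and C11orf68 with E. coli vesicles kept theirs in 20 of 20, and B3GALT6 and CCDC85B lost theirs in 3 and 4 of 20.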

Other observations

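The rows here were chosen after their values were seen, from the 84 rows called with the replicate block for E. coli vesicles, and none of them was called by edgeR without the block. The KDM4A row, named for a histone demethylase, had 108 ± 3.92 CPM in controls, 56.6 ± 14.1 with V. cholerae vesicles and 43.3 ± 14.4 with E. coli vesicles (SD, n = 3). Its blocked log2 fold change was -1.30 ± 0.28 for E. coli vesicles, and it was not called for V. cholerae vesicles. Of the 18 tested rows named for histone modifying enzymes, 9 were higher and 9 lower with E. coli vesicles and the block. Adjusted over that list alone, 4 passed as higher and 2 as lower. The HMGA1 row, named for an architectural chromatin protein, had a blocked log2 fold change of -0.73 ± 0.17, and the HNRNPA2B1 row, opposite the heterochromatin protein gene CBX3, one of 1.37 ± 0.28.

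The APOBEC3B-AS1 row, opposite the cytidine deaminase genes APOBEC3B and APOBEC3A, rose from 237 ± 55.4 to 582 ± 258 CPM (SD, n = 3). The row named for NAIP, a sensor of bacterial proteins in the inflammasome, rose from 85.2 ± 40.3 to 179 ± 19.8 CPM (SD, n = 3). Its counts are not established as NAIP's own transcript. The TMEM184A row, opposite the transcription factor gene MAFK, rose from 1089 ± 39.1 to 2243 ± 775 CPM (SD, n = 3). The BEST1 row, opposite the ferritin gene FTH1, had a blocked log2 fold change of 0.80 ± 0.17. In replicates 1 and 2 alone the log2 fold changes were 1.44 for APOBEC3B-AS1, 1.49 for NAIP, 1.28 for TMEM184A and 0.79 for BEST1. In replicate 3 the log2 ratios were 0.70, 0.49, 0.35 and 0.79 in the same order.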
